A study of Mus musculus with 44 samples.

How the data were processed

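The series profiled bone marrow-derived macrophages of C57BL/6 mice, wild type (WT) or lacking the DNA methyltransferase Dnmt3a (KO). Its 44 samples comprise 10 reduced representation bisulfite libraries (5 per genotype), 8 ATAC-seq libraries (2 per genotype and treatment) and 26 ChIP-seq samples. The ChIP-seq samples are 10 with an IRF3 antibody, 12 with an NF-kB antibody and 4 inputs, 1 input per genotype and treatment. The labels do not say which NF-kB subunit was precipitated. Per the labels' protocols, marrow cells were grown with 30 ng/ml M-CSF and 10% serum and collected between day 8 and day 10. Treated cells for ATAC-seq and ChIP-seq received 10 ng/ml lipopolysaccharide (LPS) for 6 hours, and chromatin for ChIP-seq was sheared to between 100 and 300 bp. Bisulfite, ATAC-seq and input data were not analysed here.

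The analysis started from 8 deposited peak lists, 1 per factor, genotype and treatment. Per the labels, every replicate of a group points to the same list, so each list merges its group's replicates. The IRF3 lists merge 3 samples (WT untreated), 2 (WT LPS), 2 (KO untreated) and 3 (KO LPS), and each NF-kB list merges 3. Per the submitters' processing notes, the coordinates are in mm10 and the tools include Trim Galore 0.4.5, Bismark 0.22.3, methylKit, Picard 2.8.0, deepTools 3.5.0, MACS2 2.1.1 and HOMER 4.9. Those notes give no role for each tool. The aligner, the peak-calling settings, the way replicates were merged and the threshold for keeping a peak are not given in the sources used here. The names of the deposited lists hold the words chipr and optimal, which may refer to ChIP-R, a program that combines replicates by ranks. If so, the deposited p-values and q-values, the ranks and the recovered numbers of candidate regions describe that combination and not enrichment over input. The lists have no header. Each deposited peak carries a signal value, treated here as a score without a stated normalization. It also carries a deposited p-value and a deposited q-value, which is never below the p-value. These values are the authors' own and served only to rank and filter peaks within a list. Peaks were ranked by p-value, with ties broken by signal value, width and position.

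The largest q-value in a list lay between 0.893 and 0.912, so the deposited lists were not cut at a q-value of 0.05. Between 114 and 422 peaks per list had a q-value under 0.05. The number of candidate regions behind each list was recovered as the largest value of q times rank over p in that list. Only 1 rank reached that value in the untreated WT NF-kB list and 2 in the untreated KO IRF3 list. The numbers for these lists may therefore be too low. Read depth is not given in the sources used here. A merged list has no spread between replicates, and the lists for which the number of replicates differs can differ in length for that reason. No test between groups was therefore made. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only, and the labels do not say whether replicates came from separate animals. The Dnmt3a deletion could not be checked from these lists.

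Peaks on chromosomes 1 to 19, X and Y were used, and no list held a peak elsewhere. Peaks counted as shared when they overlapped by at least 1 bp. Overlap by chance came from 1000 random placements of the first list's peaks, each kept on its chromosome and at its width. All 8 lists were also joined into regions, each being a run of overlapping peaks. Gene positions came from a table of the GRCm38.p6 assembly, the assembly named mm10, with 21887 protein-coding genes on these chromosomes. The table gives gene spans without strand or exons. Distances that were planned from transcription start sites were therefore measured from the nearer of both annotated gene ends, and exons and introns were not separated. A gene counted as having a peak when a peak lay within 10 kb of either end. Each gene list's count was set beside 10000 random lists of the same size drawn from all protein-coding genes, and the percentile is the share of random lists with a lower count. Shares of peaks inside gene spans and near gene ends were set beside 200 random placements.

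The 9 gene lists and 6 lists of markers for other cell types were written before the data were examined, as were the comparisons, their main settings and most alternatives. They hold 311 symbols, of which 304 matched a protein-coding gene. The rule for named genes was fixed at the same time. For each comparison it took the 5 best-ranked peaks present in each list alone with a gene within 100 kb, named by the nearest gene span. It also took members of the fixed lists with a peak within 10 kb, up to 6 per list where presence differed and up to 4 where both lists had one. The result for 1 gene of the fixed lists is not reported here. The planned search for binding motifs and base composition needs the genome sequence, which was not used here.

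The counting in the overlap and gene-list steps was checked on simulated peaks, planted to overlap listed peaks or to lie within 10 kb of genes. Full recovery was set by construction, so the detection of binding was not tested. In the overlap step, built on the untreated NF-kB lists, 439 and 877 peaks planted among 1462 were all recovered, and chance overlaps numbered 1 to 6. In the gene-list step, 5 and 10 genes planted among the 52 NF-kB targets were all recovered, with 1 chance hit each. Alternatives changed the overlap rule, the peak threshold, list length, the recurrent regions, the chromosomes, the distance to genes and the random background. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with the random seed 20260.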

Results

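Macrophages grown from mouse bone marrow were compared between WT and Dnmt3a KO genotypes, untreated or after 10 ng/ml LPS for 6 hours. LPS is a bacterial cell wall component that activates macrophages through Toll-like receptor signalling. IRF3 and NF-kB are transcription factors downstream of that signalling, and Dnmt3a is a de novo DNA methyltransferase. ChIP-seq recovers DNA bound by a factor, and the peaks described here are the positions reported for IRF3 and NF-kB in 4 conditions each. Each of the 8 deposited lists merges 2 or 3 replicates, so no value below has a replicate spread and no difference between lists was tested. Intervals are exact 95% binomial intervals that cover counting error only. Coordinates are in mm10.

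The IRF3 lists held 1169 peaks in untreated WT cells, 1424 in WT with LPS, 1707 in untreated KO cells and 1792 in KO with LPS. The NF-kB lists held 1462, 2494, 3065 and 2376 peaks in the same order. Median peak width ranged from 944 to 1267 bp, well above the 100 to 300 bp of the sheared fragments. Narrow peaks, under 500 bp, made up 19.6, 24.7, 25.2 and 29.4% of the NF-kB lists and 17.5, 16.3, 13.8 and 13.3% of the IRF3 lists in the same order. In untreated WT the intervals of both factors overlapped (17.6 to 21.8% for NF-kB and 15.3 to 19.8% for IRF3). Joined together, the lists formed 5605 regions, of which 2765 appeared in 1 list and 360 appeared in all 8. The 360 recurrent regions had a median width of 2472 bp and supplied between 12.0 and 31.7% of each list's peaks. Among the 100 best-ranked peaks of a list, 79 to 90 lay in a recurrent region.

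**Figure D1:**
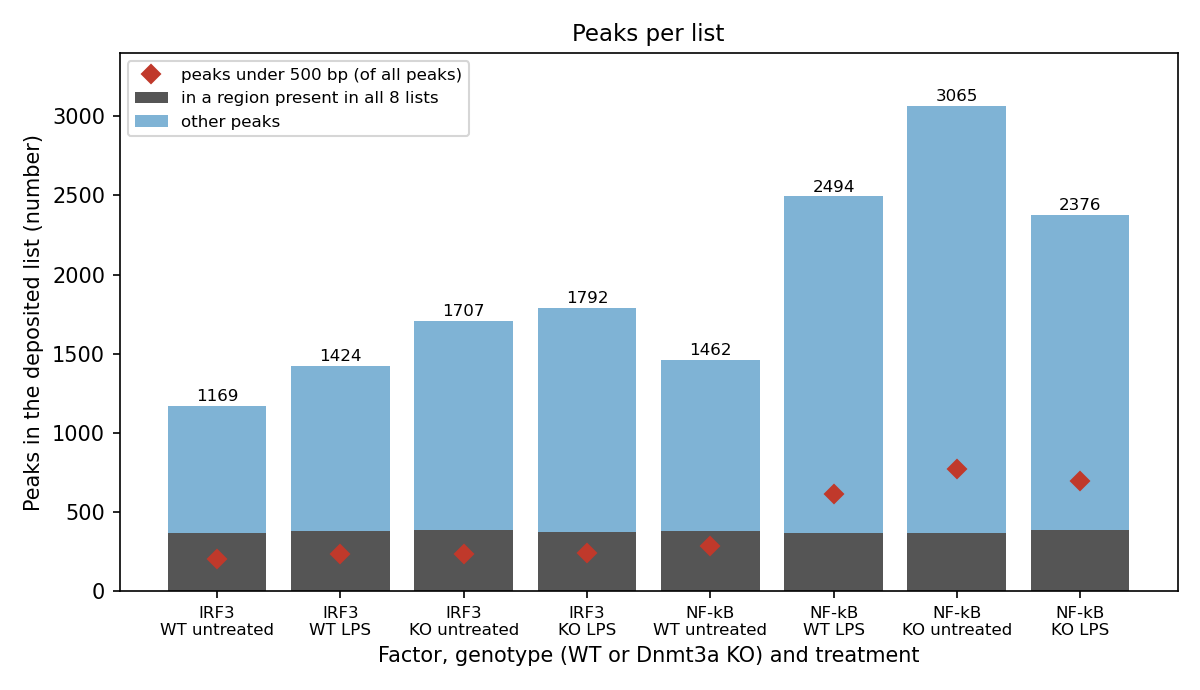
Number of peaks in each deposited list, by factor, genotype and treatment. Bars are stacked into peaks in a region present in all 8 lists (dark) and other peaks (light), and diamonds give peaks under 500 bp, which number 698 in the NF-kB KO LPS list and 239 in the IRF3 KO LPS list. The NF-kB list is longer with LPS in WT (2494 against 1462) and shorter with LPS in KO (2376 against 3065).

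The first comparison asked where each factor was found after LPS. With LPS, NF-kB peaks appeared at well-known inflammatory targets in both genotypes. In WT, 4 of the 52 NF-kB targets had a peak in the LPS list (7.69%, 2.14 to 18.5%), and none of these 4 had one in the untreated list. They were Tnfaip3, which encodes the NF-kB inhibitor A20, the mitochondrial superoxide dismutase gene Sod2, Malt1, which encodes a paracaspase of NF-kB signalling, and Bcl3, which encodes a nuclear IkB protein. In KO, 10 targets had a peak with LPS (19.2%, 9.63 to 32.5%) against 2 without. The WT count stood at percentile 98.0 of random lists and the KO count at percentile 100. Under other distances and peak thresholds the WT percentile ranged from 83.4 (q-value under 0.05) and 85.1 (within 50 kb) to 99.96 (peaks under 500 bp). The KO percentile stayed between 99.98 and 100. Drawn only from genes with a peak in any list, random lists put the WT count at percentile 14.9 and the KO count at percentile 99.7. That pool holds 11 targets, 10 of them marked by the KO LPS list itself, so by construction it favours KO with LPS over the other lists.

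Of the NF-kB targets with a peak in an LPS list, all 4 in WT and 8 of the 10 in KO had a peak under 500 bp. In WT the Tnfaip3 peak spanned 302 bp on chromosome 10 (19015399 to 19015700) and the Malt1 peak spanned 245 bp on chromosome 18 (65430411 to 65430655), 284 bp from the gene. The Sod2 peak lay inside the gene on chromosome 17 (13010180 to 13010354). In KO the same positions near Tnfaip3, Malt1, Sod2 and Bcl3 were listed. Further KO peaks lay 83 bp from Nfkbia, which encodes the inhibitor IkBa, and 43 bp from an end of Birc3, which encodes an inhibitor of apoptosis. Others overlapped ends of Lcn2, which encodes an iron-binding siderophore carrier, and Saa3, an acute-phase gene, and 1 lay 9747 bp from the cytokine gene Il1b. The q-values of these further KO peaks were 0.0830 for Lcn2, 0.221 for Birc3, 0.303 for Il1b, 0.456 for Saa3 and 0.912 for Nfkbia. The Nfkbia peak ranked 2153 of 2376 and dropped out at equal list length and at a common p-value cutoff. The pattern recognition receptor gene Tlr2 had a wide peak with LPS in KO (2648 bp) and in both untreated lists, but not in WT with LPS. Ripk2 had a peak in untreated KO cells and not in KO with LPS.

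The best-ranked NF-kB peaks present with LPS and absent without it included 1 near Fgd2 (a guanine nucleotide exchange factor gene) in both genotypes. In KO the others lay near Fth1 (ferritin heavy chain), Cebpb (a transcription factor gene), Fyb (an adaptor gene) and Tnfaip3. The Fth1 peak had a list p-value of 3.33e-07 and spanned 523 bp on chromosome 19 (9974870 to 9975392), outside the gene and 5208 bp from it. The Cebpb peak (456 bp, chromosome 2, 167777416 to 167777871) lay 86984 bp from its gene. In WT the others lay near Gm21119, Sfi1, Spin4 and Sned1. The positions near Fth1, Cebpb, Fyb and Tnfaip3 were also gained in WT, at ranks 119, 134, 642 and 389. The Sned1 position was also gained in KO, at rank 336. The WT peaks near Gm21119, Sfi1 and Spin4 were 3171, 4714 and 2520 bp wide, whereas the WT Fgd2 peak spanned 315 bp. The Gm21119 and Sfi1 positions were also listed in untreated KO cells, at ranks 10 and 1. The best-ranked NF-kB peaks found without LPS alone lay near Blcap, Fbxw4, Cdc42bpa, Pth2r and Zfp872 in WT and near Tmem18, Cmc1, Actr3b, Olfm4 and Dnah7c in KO. A gene named here is the nearest to the peak, and no effect on it was measured.

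No IRF3 peak lay near an interferon-stimulated gene, and less than 1 was expected by chance. None of the 45 matched interferon-stimulated genes, which include Ifnb1, Ifit1, Isg15 and Cxcl10, had an IRF3 peak within 10 kb of an end in any of the 4 lists (0 to 7.87% for each). Random lists gave a mean of 0.396 to 0.640 genes, so the count of 0 does not set these genes apart. The best-ranked IRF3 peaks found with LPS alone lay near Gm39469, Smgc, Sfi1, Gm40035 and Orc5 in WT and near Rhox3h, Fundc1, Spock3, Zfp980 and Tacr3 in KO. Those found without LPS alone lay near Cemip2, Spin2g, E030030I06Rik, Gm21977 and Mup20 in WT and near Mid1, Nsmce2, Gm2959, Actg1 and Tcte2 in KO. Several of these, such as the Spin, Mup, Rhox and Zfp genes, belong to families of similar copies, where reads can be shared between copies. The Gm39469 and Smgc positions found with LPS alone in WT were also listed in untreated KO cells, at ranks 16 and 57. Dnmt3b, the other de novo methyltransferase gene, had an IRF3 peak 3869 bp from an end in WT with LPS and 3792 bp from it in KO with LPS, and none in either untreated IRF3 list. Those peaks ranked 1237 of 1424 and 1146 of 1792.

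In total, 948 of 2494 NF-kB peaks of WT with LPS (38.0%, 36.1 to 39.9%) overlapped the untreated list, leaving 1546 found with LPS alone and 487 found without it alone. In KO, 1477 of 2376 peaks (62.2%, 60.2 to 64.1%) overlapped, leaving 899 and 1656. For IRF3 the shared part was 657 of 1424 peaks in WT (46.1%, 43.5 to 48.8%) and 1006 of 1792 in KO (56.1%, 53.8 to 58.5%). Seen from the untreated lists, the shared parts were 66.7% in WT and 46.0% in KO for NF-kB, and 54.9 and 60.3% for IRF3. Random placement gave at most 17 shared peaks in any of these 4 comparisons. Peaks found in 1 treatment alone were narrower than shared ones, with or without LPS. For NF-kB in KO the medians were 419 bp with LPS alone, 620.5 bp without it alone and 1265 bp for shared peaks, and in WT 714, 657 and 1623 bp. For IRF3 they were 846, 864 and 1529 bp in KO and 923, 782 and 1722 bp in WT. Narrow peaks of the LPS list overlapped the whole untreated list in 9.59 to 29.8% of cases, and its narrow peaks in 3.74 to 9.21%, settings chosen after seeing the data. Without the recurrent regions the shared parts were 26.7 to 55.1%.

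**Figure D2:**
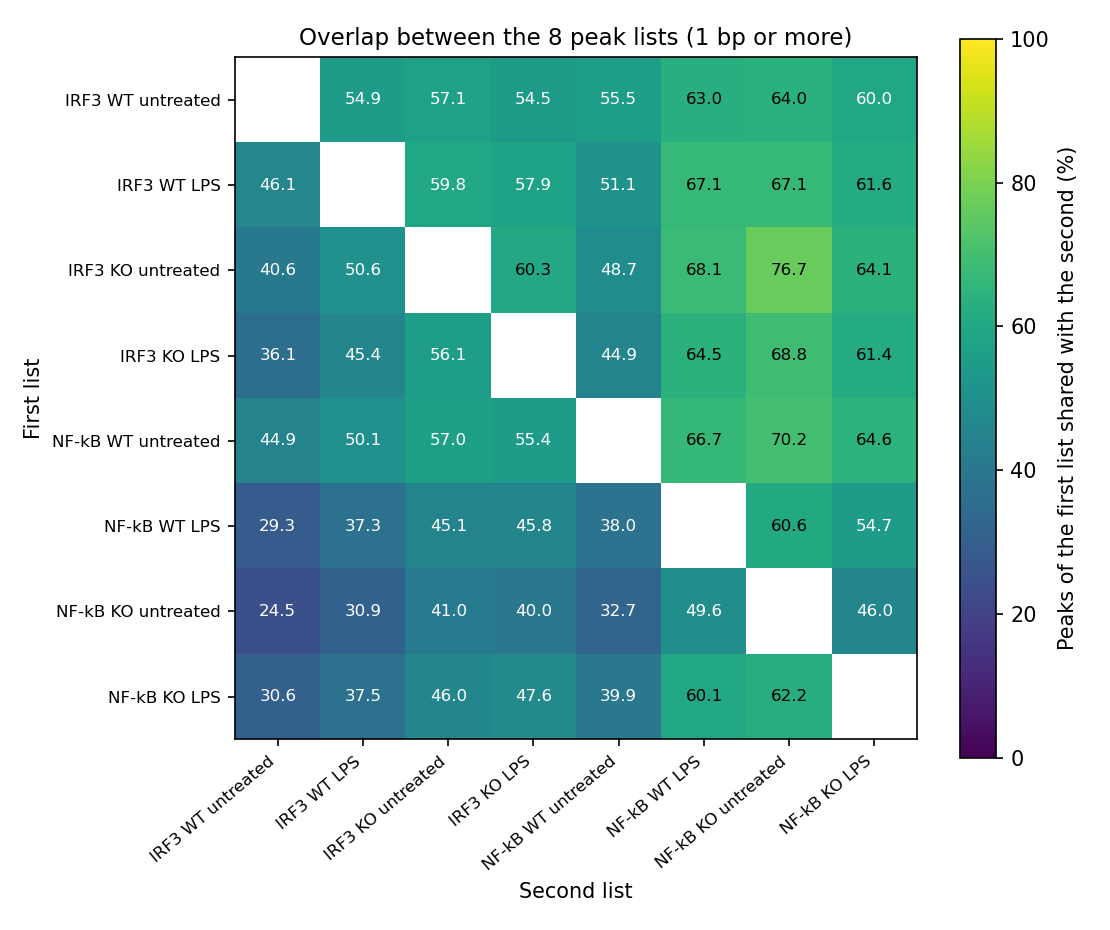
Percent of peaks of the first list (rows) that overlap a peak of the second list (columns) by at least 1 bp, for all pairs of the 8 lists. Pairs from the same factor have a median of 54.8% and pairs from different factors a median of 50.6%.

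The second comparison asked how occupancy differed between Dnmt3a KO and WT cells. With LPS, NF-kB peaks marked more inflammatory targets in KO than in WT. All 4 targets with a peak in WT also had one in KO, and 6 more had one in KO alone (Il1b, Nfkbia, Birc3, Tlr2, Saa3 and Lcn2). No target had one in WT alone within 10 kb, while within 50 kb Relb did. Among macrophage identity genes, Adgre1, which encodes a macrophage surface receptor, and Lyz1, a lysozyme gene, had narrow NF-kB peaks in KO with LPS and none in WT with LPS. B2m, the MHC class I light chain gene, had a 144 bp peak 54 bp from an end in KO, and Ciita, the MHC class II transactivator gene, had a 548 bp peak in WT. The q-values were 0.0490 for Adgre1, 0.593 for Lyz1, 0.721 for B2m and 0.904 for Ciita. With a q-value under 0.05 required, 3 targets remained in KO (Tnfaip3, Sod2 and Malt1) and 1 in WT (Sod2).

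The best-ranked NF-kB peaks of KO with LPS absent from WT with LPS lay near Tcte2, Sema4d (a semaphorin gene), Ppp1r9a, Saa1 (an acute-phase gene) and Vmp1 (an autophagy gene). The Sema4d peak spanned 150 bp inside the gene on chromosome 13 (51740932 to 51741081), and the Saa1 peak spanned 158 bp on chromosome 7 (46745845 to 46746002), 2664 bp from the gene. Peaks of WT absent from KO lay near Ccr1 (a chemokine receptor gene), Gm40035, Akap9, Pak3 and Olfr76. By the naming rule a gene can lie up to 100 kb from its peak. The Tcte2 and Ccr1 peaks lay 61201 and 36036 bp from their genes. Without LPS, the best-ranked NF-kB peaks of KO alone lay near Sfi1, Gm21119, Smo (the Hedgehog pathway receptor gene), Eef2 (a translation elongation factor gene) and Sox17, and those of WT alone near Zfp600, Olfr108, Spock3, Cdc42bpa and Pth2r. The positions near Sfi1 and Gm21119 were also listed in WT with LPS. The Sox17 peak lay 62222 bp from its gene, while the Smo and Eef2 peaks lay inside theirs. Among fixed lists, untreated NF-kB peaks lay near Ripk2, Ddx58 (the RNA sensor RIG-I gene) and Tbk1 (a kinase gene upstream of IRF3) in KO alone and near Sp100 in WT alone. Those 4 peaks ranked between 1030 and 2632 in their lists.

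IRF3 peaks of untreated KO cells absent from untreated WT cells were led by peaks near Gm39469, Stam2, Vps45, Smgc and Mid1. Those of WT alone were led by peaks near Gm17019, Speer4c, Gm9758 and E030030I06Rik. The positions near Gm39469 and Smgc were also listed in WT with LPS. With LPS, IRF3 peaks of KO alone were led by peaks near Itgb1 (an integrin gene), Mup20, Tmem125, Afm and Nbea. Those of WT alone were led by peaks near Cdkn1a (the cell cycle inhibitor p21 gene), Gm21190, Magea4, Ly6c2 and Gm17019. The Cdkn1a peak spanned 2155 bp on chromosome 17 (29101822 to 29103976), 1100 bp from the gene. The Itgb1 peak lay 43224 bp from its gene. Kitl, a stromal marker, had an IRF3 peak in KO with LPS alone, ranked 1673 of 1792 with a q-value of 0.903. IRF3 peaks near Dusp5, a phosphatase gene, were present in untreated KO and absent in untreated WT.

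By number, 1428 of 2376 NF-kB peaks of KO with LPS overlapped the WT list (60.1%, 58.1 to 62.1%), against 1002 of 3065 without LPS (32.7%, 31.03 to 34.4%). For IRF3 the shared part was 814 of 1792 with LPS (45.4%, 43.1 to 47.8%) and 693 of 1707 without (40.6%, 38.3 to 43.0%). Seen from the WT lists, the order was reversed for NF-kB, with 54.7% shared with LPS and 70.2% without, and the IRF3 shares were 57.9 and 57.1%. These shares depend on list length, and the untreated NF-kB lists hold 3065 peaks in KO and 1462 in WT. Random placement gave at most 16 shared peaks. Cut to the 1462 best-ranked peaks, the NF-kB lists shared 61.0% with LPS and 50.7% without. Narrow KO peaks overlapped the whole WT list in 8.15 to 31.2% of cases, and its narrow peaks in 4.14 to 13.2%. Without the recurrent regions the shared parts were 31.5% with LPS and 23.8% without for IRF3, and 52.5 and 23.7% for NF-kB.

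**Figure D3:**
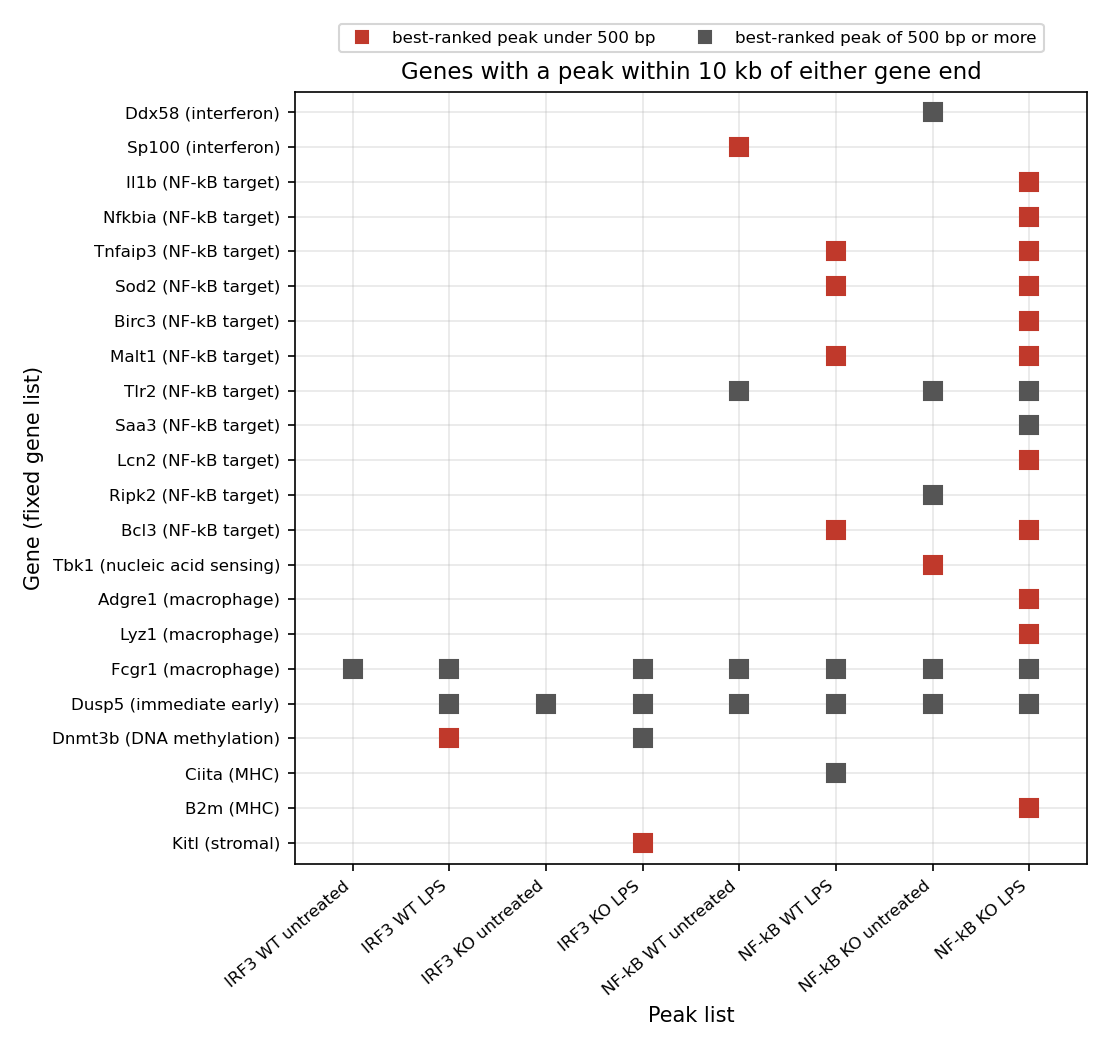
Members of the fixed lists reported here (rows) with a peak within 10 kb of either gene end in each of the 8 lists (columns). Squares are coloured by the width of the best-ranked peak, under 500 bp or wider. The NF-kB KO LPS list marks 10 NF-kB targets and the WT LPS list 4, while peaks near Fcgr1 and Dusp5 are at least 500 bp wide and present in 7 lists each.

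The third comparison asked whether the genotypes gained the same positions with LPS. NF-kB gained peaks near Tnfaip3, Sod2, Malt1, Bcl3, Fgd2, Fth1, Cebpb, Fyb and Sned1 in both genotypes. Gains near Il1b, Nfkbia, Birc3, Saa3 and Lcn2 were listed in KO alone. Of the 1546 NF-kB peaks found with LPS alone in WT, 204 were also found with LPS alone in KO (13.2%, 11.5 to 15.0%). Of the 899 such KO peaks, 207 were found with LPS alone in WT (23.03%, 20.3 to 25.9%). Random placement gave at most 5 such peaks, and drawing as many peaks at random from both LPS lists gave 298 to 376. Those draws included peaks shared with the untreated lists, which peaks found with LPS alone exclude by definition. The draws therefore cannot show whether the genotypes shared fewer gains than chance. A further 692 of the 1546 WT peaks (44.8%) were already in the untreated KO list. For IRF3, 94 of 767 WT peaks (12.3%, 10.0 to 14.8%) were found with LPS alone in KO. Of the shared gains, 41.7% were narrow for NF-kB and 12.8% for IRF3.

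The fourth comparison set both factors side by side in the same condition. Fcgr1, an Fc receptor gene of macrophages, had a peak in 7 of the 8 lists, 9505 to 9984 bp from an end of the gene and 2147 to 2733 bp wide. Dusp5 also had wide peaks of both factors in 7 lists. No NF-kB target gene had an IRF3 peak in any condition, where random lists gave a mean of 0.440 to 0.747 genes. Overall overlap was large, at 649 of 1169 IRF3 peaks in untreated WT (55.5%, 52.6 to 58.4%) and 955 of 1424 in WT with LPS (67.1%, 64.6 to 69.5%). In KO it was 1309 of 1707 without LPS (76.7%, 74.6 to 78.7%) and 1101 of 1792 with LPS (61.4%, 59.1 to 63.7%). Seen from the NF-kB lists, the shares were 44.9% in untreated WT, 37.3% in WT with LPS, 41.0% in untreated KO and 47.6% in KO with LPS, so the order of the conditions depends on the side taken. Random placement gave at most 14 shared peaks. Lists of different factors shared a median of 51.5% of peaks in the same condition and 50.6% in different conditions. At equal list length the medians were 57.1 and 52.1%. Overlap of this size was therefore not particular to lists of the same condition. Narrow IRF3 peaks overlapped the whole NF-kB list in 11.8 to 52.3% of cases, and its narrow peaks in 7.33 to 13.2%. Without the recurrent regions the shared parts were 35.0 to 70.2%.

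Of the remaining fixed lists, none of the 16 lipid handling genes had a peak within 10 kb in any list, and no T cell, B cell, neutrophil, dendritic cell or erythroid marker had one. Random lists of these sizes gave a mean of 0.0782 to 0.369 genes, so a count of 0 says little for any of them. Among the 24 immediate early genes Dusp5 alone had peaks, and among the 21 matched nucleic acid sensing genes Tbk1 alone. Macrophage identity genes reached 3 of 30 in the NF-kB KO LPS list (Adgre1, Lyz1 and Fcgr1), at percentile 97.9 of random lists, and 1 or 0 in the other lists. No other list passed percentile 90 in any of the 8 peak lists except the NF-kB targets named above.

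Peaks of both factors lay outside genes more often than randomly placed ones. Between 26.6 and 31.5% of peaks overlapped a protein-coding gene span, against a mean of 39.4 to 39.8% for random placement. Between 1.23 and 2.99% lay within 1 kb of a gene end, against 4.49 to 4.92%. The share near gene ends was highest for IRF3 in untreated WT (2.99%, 2.09 to 4.14%) and, among NF-kB lists, in KO with LPS (2.15%, 1.60 to 2.81%). Genes with a peak within 10 kb of an end numbered 439 for NF-kB in WT with LPS and 433 in KO with LPS, from lists of 2494 and 2376 peaks.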

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

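All tests in this part were chosen after the lists had been seen. The results below were picked out because the change with LPS had opposite signs in WT and KO. Each group is a single merged list, so the difference between the genotypes was not tested.

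The number of NF-kB peaks rose by 1032 with LPS in WT and fell by 689 in KO, a difference between the changes of -1721 peaks. Covered sequence moved the same way, by 1.09 Mb in WT and -0.792 Mb in KO, a difference of -1.89 Mb. Most of both changes in number lay in peaks of 500 bp or more. Wide peaks alone do not account for the rise in WT, where peaks under 500 bp went from 287 to 615 (2.14 times). In KO peaks under 500 bp went from 773 to 698 (0.903 times), a small part of the fall. The LPS list held 47.5% of both KO counts together, with an interval of 44.9 to 50.04%. Whether wide peaks alone account for the fall in KO therefore stays open. The number of candidate regions behind the lists moved the same way (0.584 times in KO and 1.94 times in WT). For IRF3 it fell while the list grew in WT with LPS (0.969 against 1.22 times). The same held in untreated KO over WT (0.717 against 1.46 times). The numbers for untreated WT NF-kB and untreated KO IRF3 may be too low, so 1.94 may be too high and 0.717 too low. The part of the authors' calling or merging step therefore stays open, as does a genotype effect, untested.

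The median width of IRF3 peaks changed by -22 bp with LPS in WT and by 27.5 bp in KO, a difference of 49.5 bp. The share of IRF3 peaks inside a gene span changed by -0.673 percentage points in WT and 0.315 in KO, a difference of 0.989 points. The share within 1 kb of a gene end changed by -0.747 points in WT and 0.388 in KO, a difference of 1.13 points. The IRF3 lists merge 3 replicates without LPS and 2 with it in WT, and 2 without and 3 with it in KO. Each of these 3 IRF3 changes therefore has the sign of the change in replicate number, which is confounded with the comparison.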

How the results depend on the processing

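The 2 settings for peaks under 500 bp and those for the gene span with 10 kb on both sides, for a q-value under 0.05 and for a common p-value cutoff were chosen after seeing the data; the others were chosen before. No paired analysis was possible because each deposited list merges the replicates of its group, and for the same reason leaving out each replicate in turn could not be done. The motif alternatives were not run, since the genome sequence was not used here. Causes of the shifts below were not tested except where the setting's construction gives them. Values are in the order IRF3 WT, IRF3 KO, NF-kB WT and NF-kB KO for LPS against untreated, IRF3 untreated, IRF3 LPS, NF-kB untreated and NF-kB LPS for KO against WT, and WT untreated, WT LPS, KO untreated and KO LPS for IRF3 peaks shared with NF-kB.

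With an overlap of at least 50% of both peaks required, the LPS comparisons shared 39.4, 48.2, 32.4 and 50.9%, the KO comparisons 33.2, 39.0, 27.1 and 49.5%, and the factors 47.3, 56.3, 63.6 and 51.5%. In the strictest 50% of each list by p-value, the LPS comparisons shared 55.3, 61.7, 41.0 and 66.1%, the KO comparisons 43.6, 48.5, 34.4 and 62.8%, and the factors 61.7, 71.1, 78.1 and 68.6%. In lists cut to the length of the shortest list of the factor (of both factors for co-occupancy), the LPS comparisons shared 52.4, 61.6, 52.5 and 59.1%, the KO comparisons 49.96, 54.8, 50.7 and 61.0%, and the factors 50.9, 57.2, 63.6 and 58.8%. Without the regions present in all 8 lists, the LPS comparisons shared 26.7, 44.8, 27.5 and 55.1%, the KO comparisons 23.8, 31.5, 23.7 and 52.5%, and the factors 35.0, 55.1, 70.2 and 51.6%. With both lists cut to peaks under 500 bp, which removes wide partners, the LPS comparisons shared 6.90, 9.21, 3.74 and 7.31%, the KO comparisons 4.68, 5.86, 4.14 and 13.2%, and the factors 7.35, 7.33, 13.2 and 10.0%. With the first list alone cut to such peaks, the LPS comparisons shared 15.5, 19.2, 9.59 and 29.8%, the KO comparisons 21.7, 15.1, 8.15 and 31.2%, and the factors 11.8, 24.1, 52.3 and 22.6%. Counting peaks within 500 bp of each other as shared kept all 12 shares inside their main intervals. Using all chromosomes left them unchanged by construction, since no list held a peak elsewhere.

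The share of WT gains with LPS that KO also gained was 13.2% for NF-kB and became 10.7% with 50% overlap required and 15.1% at equal list length. For IRF3 it was 12.3% and became 2.31% with all lists cut to peaks under 500 bp. Both stayed inside their main intervals under the other settings, including 12.5% for NF-kB among peaks under 500 bp. By construction, 2 of those settings could hardly move them. All chromosomes held the same peaks, and without the recurrent regions 1543 of 1546 NF-kB and 766 of 767 IRF3 gains in WT remained. Taking the strictest 50% left, by construction, 585, 712, 854, 896, 731, 1247, 1533 and 1188 peaks (IRF3, then NF-kB, in the order of the co-occupancy conditions). Widening the distance to a gene end to 2 kb raised the location shares, by construction, to 5.05, 4.14, 3.22, 3.68, 2.804, 3.17, 2.97 and 3.54% in the same order, and location shares at equal list length stayed inside their intervals.

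The count of NF-kB targets with an NF-kB peak was 1, 4, 2 and 10 in untreated WT, WT with LPS, untreated KO and KO with LPS. Within 2 kb of a gene end it was 0, 2, 0 and 6, and within 50 kb it was 2, 7, 4 and 14. With a q-value under 0.05 it was 0, 1, 0 and 3, and among peaks under 500 bp 0, 4, 0 and 8. At equal list length it was 1, 3, 1 and 9, over the gene span and 10 kb on both sides 1, 5, 2 and 12, and at a common p-value cutoff 4 and 9 in the LPS lists. KO exceeded WT with LPS in each of these settings. Interferon-stimulated genes with an IRF3 peak stayed at 0 except within 50 kb, where Sp100 gave 1 in untreated WT, 1 in untreated KO, 0 in WT with LPS and 1 in KO with LPS. Against random lists drawn from genes with a peak in any list, the NF-kB target counts stood at percentiles 3.09, 14.9, 0.22 and 99.7, where all protein-coding genes gave 55.4, 98.0, 66.8 and 100. The first of these pools holds 11 targets, 10 of them marked by the KO LPS list, so by construction it favours that list. Read depth per sample is not given in the sources used here, so what depth limits is unknown, and low-ranked peaks rest on q-values up to 0.912.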

Other observations

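The tests and genes in this part were chosen after the lists had been seen, except the test of the share near clustered gene families against random placement. The NF-kB target list and the equal-length setting were fixed before, but their use here to weigh an explanation was not. A set of 101 regions was present in the NF-kB LPS lists of both genotypes and in no other list. Their median width was 446 bp, against 2472 bp for the regions present in all 8 lists, and 32.7% lay within 10 kb of a gene end (23.7 to 42.7%), against 22.0% on average and at most 30.7% in random placements. By the sum of both ranks, the first 10 had as nearest genes Fth1 (ferritin heavy chain), Fgd2, Cebpb (2 regions), Zeb2, Fam107a, Tnfaip3, Socs3, Sned1 and Sod2, with Zeb2 1253558 bp away. Nearest genes of the other regions ranged from Nlrp3, the inflammasome sensor gene, and Ptges, a prostaglandin synthase gene, to the olfactory receptor genes Olfr502 and Olfr1168 and the vomeronasal receptor genes Vmn2r7 and Vmn2r27. No test of gene function was run on this set. The matching set for IRF3 held 12 regions with a median width of 1594 bp. The NF-kB lists of untreated cells shared 38 regions found in no other list, those of KO in both treatments 99, and those of WT in both treatments 21.

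The first pattern weighed is the 360 regions present in all 8 lists. Binding of both factors close to gene ends is argued against by the tables as the source of most of these regions. A share of 15.3% lay within 10 kb of a gene end (11.7 to 19.4%), against 22.6% on average in random placements. Such binding stays open for the 55 regions that lay that near. Reads shared between near-identical copies were weighed through clustered gene families, defined as at least 5 protein-coding genes with the same leading letters within 500 kb. Gm and Rik genes were left out, and sequence identity was not measured. Of the regions, 91.1% lay over 100 kb from any such family (87.7 to 93.8%). This argues against shared reads near these families as the source of most regions, but leaves shared reads between other copies open. Such families stay open for a part, with 8.89% nearer against 5.64% on average and at most 9.17% in random placements. In whole lists, 7.66 to 11.1% of the peaks lay that near. Signal that depends neither on the antibody nor on the treatment stays open: lists cut to equal length shared a median of 53.3% of peaks with lists of the other factor (57.1% in the same condition, 52.1% in another) and 55.3% with lists of the same factor, but regions in all lists raise each share by construction. Binding of both factors far from genes was not tested.

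The second pattern is the larger number of NF-kB targets with a peak in KO with LPS than in WT with LPS, 10 against 4. A longer list is argued against, since the KO list is the shorter one and the difference at equal list length was 6 genes (9 against 3). The authors' p cutoff, which differs between the lists, is argued against as the whole source, since the difference at a common p-value cutoff was 5 genes (9 against 4). Whether NF-kB sites in general rank higher in the KO LPS list stays open: 73 of the 101 regions specific to both NF-kB LPS lists had the better relative rank in KO (72.3%), but the lists differ in length and cutoff and the regions include some of the targets, so this decides nothing. Stronger binding in KO cells and better enrichment of those libraries were not separated.

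The X chromosome held 45 of the 360 regions present in all 8 lists, or 0.263 per Mb, against 0.0515 to 0.179 per Mb on the 19 autosomes. Peaks in general were frequent there too: X held 12.5% of these regions (9.27 to 16.4%) and 8.96 to 10.9% of the peaks of each list.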
